A study of Lactobacillus delbrueckii subsp. bulgaricus with 2 samples.

How the data were processed

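The series measured RNA in single cells of Lactobacillus delbrueckii subsp. bulgaricus with the M20 Genomics VITA microbial assay, in which random primers start reverse transcription inside fixed cells and droplets add a cell barcode. There were 2 libraries, 1 per group, so n = 1 in each. The control was a culture grown for 13 h at 37 °C in MRS, a rich broth for lactobacilli. The rifampicin library came from a culture grown the same way to which 0.64 mg/ml rifampicin was added for 3 h, so the drug and the additional hours cannot be told apart.

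The deposited matrices hold whole-number counts per feature and barcode, with a feature list and a barcode list for each library. Per the submitters' processing notes the tool was STARsolo; its version, the genome build, the annotation, the barcode filter and the treatment of reads that match several places are not stated, and neither the labels nor the files say whether the counts are deduplicated molecules. Gene names were taken from the deposited feature lists alone. They are names of the nearest homolog, some from other organisms, and 335 of the 2021 gene features used share their name with another feature, so the feature identifier stands beside such names. The lists give no positions, lengths, strands or products.

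The deposited counts of the 2 libraries were not made alike. Both files list the same 2025 gene features, but the control file lists no rRNA, tRNA or other non-coding feature, while the rifampicin file adds 27 rRNA, 94 tRNA and 30 features with an nc identifier. Features gene45, gene46, gene47 and gene48 held 84.0% of the control counts and 0 of the rifampicin counts. The main denominator was therefore the sum over the other 2021 gene features, which was chosen after the files were seen; the denominator written down before then, with those 4 features, is given as an alternative. A run of features from gene975 to gene1008 carried the same names in mirrored order as gene1018 to gene1051 (18 named pairs; the next best mirror had 3). These 68 features form what is called the mirrored block here, and reads shared between such copies, which could not be looked for without sequence, would make their counts uncertain.

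Counts were summed over all deposited barcodes per library and gene and divided by the library's sum over the 2021 features to give counts per 1000000 gene counts (CPM). The ratio of rifampicin to control CPM has an exact conditional binomial 95% interval, and shares have exact Clopper-Pearson intervals. A gene at 0 in one library was set to 3 counts in that library, and its ratio is a bound. All intervals and floors cover counting error only. They take each count as independent, so they are too narrow for genes whose counts clump in barcodes. With 1 library per group there was no test and no replicate check: no p-value, standard error or number of significant genes was computed, and all comparisons describe these libraries, not the conditions. Genes with at least 50 counts over both libraries were compared (1756 genes), with a 2-fold size rule. The median gene had a log2 CPM ratio of 1.31, and other scalings shifted that median by more than 0.1, so values are given relative to the median gene unless CPM is named.

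Before the data were examined, 23 gene lists, the rule for named genes and the alternatives were fixed. Named genes were the 12 highest and 12 lowest with a symbol, ranked by the interval bound nearest to no difference, the 3 highest and 3 lowest of all features, the 5 most abundant per library, up to 4 members per list (the 2 with most counts and the 2 with the largest absolute log2 ratio), rpoA, rpoB, rpoC, rpoD, groL, groS, dnaK, clpP, tuf and fusA, up to 5 leading genes per cluster and the 8 most variable genes per library. The part of this rule before clusters and variability took 107 genes; other genes named in the text were chosen after their values were seen, and the text says so. A list's median was placed among 10000 random lists of the same size drawn from 10 bins of mean CPM over both libraries; lists with under 5 tested members got no percentile. Its counting interval came from 200 Poisson redraws of all counts.

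For values per cell, each barcode was taken as a cell as deposited; no doublet caller was run, because no feature marks a mixed barcode in a culture of 1 strain. Cells were thinned without replacement to 24 gene counts, the lower quartile of the shallower library, leaving out 209 control and 1092 rifampicin barcodes. Variability was variance over mean at that depth, divided by the mean of 20 sets of cells redrawn from the library's pooled profile. For clusters, each count went at random to one of 2 portions; cells with at least 20 counts in the first portion were clustered on it (500 variable genes, 10 principal components, 15 neighbours, Leiden at resolution 1), and folds came from the held-out portion, with redrawn cells as reference. Clusters have numbers only.

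Each step was tested on simulated data. For the comparison of rifampicin with control, counts for the gene features were drawn at the real library sizes with 200 genes changed. Genes raised 4-fold gave a median of 3.85-fold, genes raised 2-fold gave 1.92-fold, and the interval held the true ratio for 96.2% of 1526 unchanged genes. The draws followed the Poisson counting that the interval assumes, so this coverage says nothing about counts that clump in barcodes. Of 200 unchanged lists, 2% fell outside the 2.5th to 97.5th percentile. With the control library's depths, 165 steady genes had a median relative variance of 1.00. With the rifampicin library's depths, clusters mostly of a simulated second state recovered 63.1% of its 740 cells, so weak states can be missed. With each gene counted at most 1 time per cell, 20 genes raised together 6-fold gave no cluster past a held-out fold of 3, and 20-fold gave 2.

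The alternatives were CPM over all features, the median gene set to 1, CPM without the 10 most abundant genes, minimums of 20 and 200 counts, no minimum with 0.5 added, barcodes with at least 100 counts, removal of the 5% deepest barcodes, equal weight per cell, thinned cells, a 1.5-fold threshold, the whole interval past 2-fold, thinning at the median depth, no thinning, and other cluster settings. Those added later were the denominator with the 4 control-file features, removal of the mirrored block and of features at 0, rifampicin barcodes with at least the lowest control total, removal of rifampicin barcodes whose first 16 bases occurred with every last 4 bases, counting each gene at most 1 time per cell (for ratios, and for clusters before the split of counts), and random lists matched on control CPM. For ratios, lists and shares of the most abundant genes, the share p of thinned cells with a gene was converted to -ln(1 - p), the mean under Poisson counting. For clusters there was no such conversion. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.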

Results

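The data are single-cell RNA counts from cultures of Lactobacillus delbrueckii subsp. bulgaricus, a lactic acid bacterium used for yogurt. A 13 h culture was the control, and a culture grown the same way with 3 h of rifampicin, which binds RNA polymerase and blocks the start of transcription, was the treated group. Each group had 1 library and no replicate. The series title places the comparison in a study of protein aggregation, translation fidelity and cross-tolerance. The control library held 3535 barcodes and 2936289 counts, of which 468749 fell in the 2021 gene features used. The rifampicin library held 4551 barcodes and 1292782 counts, of which 620358 fell in those features. The median barcode had 134 gene counts over 80 genes in the control and 42 gene counts over 34 genes after rifampicin.

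After rifampicin, the transcripts that dominated the control took a smaller share of the gene counts. The groL transcript (gene1493), which encodes the chaperonin GroEL, made up 10.2% of control gene counts (95% interval 10.1 to 10.3) and 1.65% after rifampicin (1.62 to 1.68). The transcript of gap (gene581), for glyceraldehyde-3-phosphate dehydrogenase of glycolysis, went from 9.36% to 3.67%, and that of tuf (gene722), for elongation factor Tu, from 3.13% to 1.13%. These shares depend on the denominator: of all counts, with the features counted in 1 file alone, gap took 1.49% in the control and 1.76% after rifampicin, and tuf also changed side. The 100 most abundant genes of each library took 64.8% of the gene counts in the control and 34.6% after rifampicin. Across genes, which are not independent replicates, Spearman's rho between control and rifampicin CPM was 0.555.

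Of 1756 genes with enough counts, 996 were at least 2-fold higher and 147 at least 2-fold lower in CPM after rifampicin. Relative to the median gene, whose CPM was 2.48-fold higher, 560 were at least 2-fold higher and 504 at least 2-fold lower. The share of higher genes among those past 2-fold was thus 87.1% by CPM and 52.6% relative to the median gene. With all features of each file in its denominator, 1534 genes were higher and 5 lower. That adds the 4 control-file features to the control and rRNA, tRNA and nc features to the rifampicin library at the same time. With the 4 control-file features alone added, 1705 were higher and 2 lower. Under those denominators the CPM ratio of 11 and of 32 of the 83 named genes past 2-fold changed side, each of them lower in the main scaling. Values below are therefore relative to the median gene, which no choice of denominator alters. A gene lower by this measure can have an unchanged or larger share of gene counts, as the median gene was 2.48-fold higher. The reference also depends on the genes tested: with a minimum of 200 counts the median log2 CPM ratio was 0.91.

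**Figure D1:**
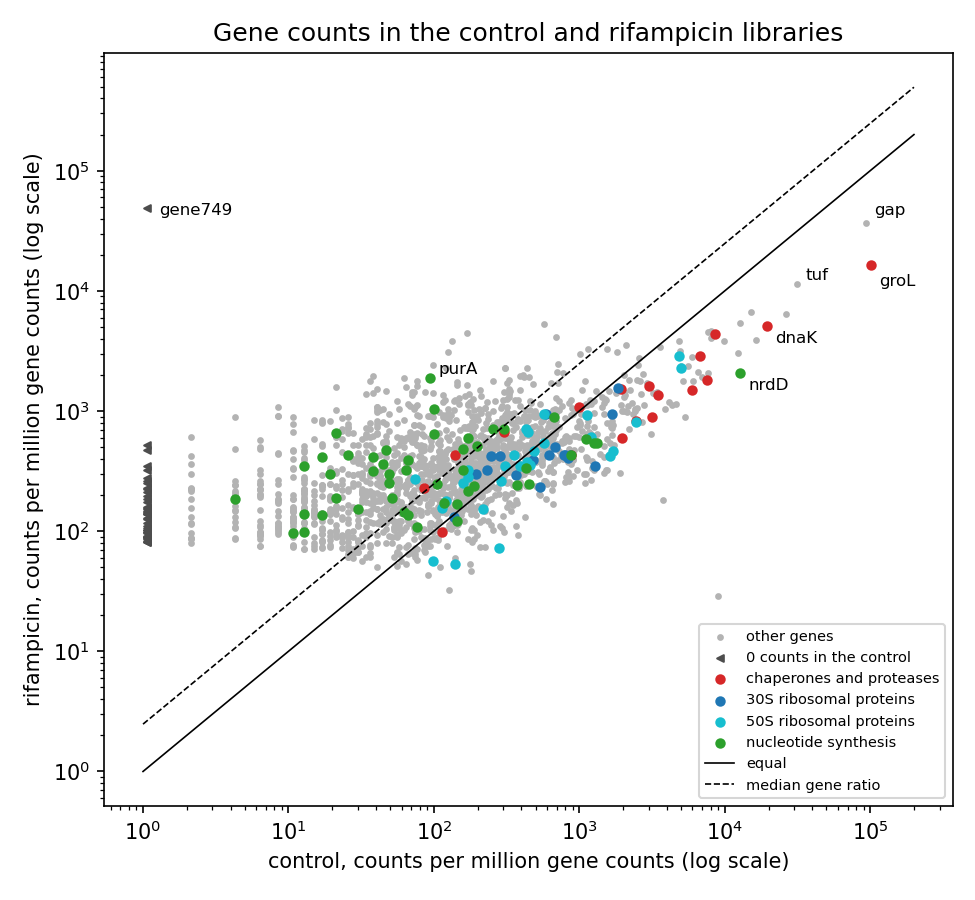
Counts per 1000000 gene counts of 1756 genes in the control library (x axis, log scale) and the rifampicin library (y axis, log scale), 1 point per gene, with 4 gene lists in colour and the 42 genes at 0 in the control as triangles at the left. Abundant control transcripts such as groL and gap lie below the line of equality, and the median gene lies 2.48-fold above it.

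A median below the median gene was common to 19 of the 23 lists, so it sets no list apart by itself. Chaperone and protease genes, which fold proteins or remove damaged ones, were among these lists. Of 18 tested members, 15 were at least 1.5-fold lower relative to the median gene and 0 were higher, with a list median of -2.44 on the log2 scale (counting interval -2.57 to -2.37). Together they took 16.9% of control gene counts and 4.18% after rifampicin. groL was 15.3-fold lower (log2 -3.93, interval -3.97 to -3.90), its partner groS (gene1494) 9.90-fold lower, the Hsp70 gene dnaK (gene1206) 9.50-fold lower and the surface protease gene htrA (gene129) 10.4-fold lower. The protease gene clpP (gene572) was 4.65-fold lower. Members chosen after their values were seen included clpX at -3.13 and the disaggregase gene clpB at 0.32. The list lay at percentile 0.75 of random lists matched on mean expression, and at 6.98 of lists matched on control expression.

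Genes of the translation machinery also had list medians below the median gene; of these lists, those of ribosomal proteins alone lay outside the middle 95% of random lists matched on mean expression. Of 18 tested 30S ribosomal protein genes 17 were at least 1.5-fold lower and 0 higher, with a median of -1.68, percentile 0.43 (9.12 when matched on control). Of 28 tested 50S genes 26 were lower and 0 higher, with a median of -1.48, percentile 0.25 (8.73 when matched on control). By CPM, 7 of the 50S genes were at least 1.5-fold higher and 9 lower, and 3 of the 30S genes higher and 7 lower. rpsO (gene719) was 9.06-fold lower, rpsB (gene1239) 2.96-fold, rplK (gene1542) 5.46-fold and rplA (gene1541) 4.13-fold. Among translation factors 17 of 19 were lower and 1 higher, with a median of -1.48 and percentile 3.19 (26.3 when matched on control). tuf was 6.84-fold lower, the elongation factor G gene fusA (gene355) 5.29-fold and the initiation factor gene infC (gene1388) 7.74-fold. Aminoacyl-tRNA synthetase genes, which charge tRNAs and proofread that step, had 22 of 25 members lower, 1 higher, a median of -1.26 and percentile 24.5 (91.4 when matched on control). The 1 higher member was Asns (gene863), an asparagine synthetase homolog that the name rule took in. ileS (gene694) was 2.97-fold lower and leuS (gene1451) 1.32-fold higher, short of the 1.5-fold rule. tRNA modification genes had 10 of 19 lower and 3 higher, a median of -0.61 and percentile 13.3 (45.3 when matched on control).

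The target of the drug, RNA polymerase, was measured by 9 features, of which 5 were at least 1.5-fold lower and 1 higher relative to the median gene (median -0.66, percentile 44.5, and 86.5 when matched on control). rpoB (gene348), the subunit that binds rifampicin, was 3.81-fold lower and took 0.490% of control and 0.319% of rifampicin gene counts. rpoC (gene349) was 2.61-fold lower and rpoA (gene381) 1.58-fold lower, although rpoA was at 0.25, above the median gene, with each gene counted at most 1 time per cell. By CPM, rpoA was higher at a log2 ratio of 0.65 and rpoC was at -0.08. By CPM, 5 of the 9 features were at least 1.5-fold higher and 3 lower. The sigma factor features named sigA were at 0.17 (gene1141), 0.47 (gene1142) and 0.67 (gene1143), and no feature was named rpoD. Of 8 tested elongation, termination and RNA decay genes 5 were lower and 0 higher (median -1.21, percentile 4.57, and 20.5 when matched on control).

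In central metabolism, 12 of 18 glycolysis and lactate genes were lower and 2 higher (median -1.82, percentile 14.1, and 48.6 when matched on control), with the lactate dehydrogenase gene ldhA (gene90) 10.1-fold lower, gap 6.31-fold and the enolase gene eno (gene1186) 5.66-fold. All 6 sugar uptake genes were lower (median -2.73, percentile 3.155, and 8.44 when matched on control), among them ptsI (gene526) at 7.75-fold and the beta-galactosidase gene lacZ (gene1106) at 4.23-fold. All 8 F0F1 ATPase genes were lower (median -1.73, percentile 24.5, and 80.3 when matched on control), with atpD (gene656) 3.13-fold lower. Fatty acid synthesis stood apart under both ways of matching: 12 of 14 genes were lower and 1 higher, with a median of -1.28, percentile 0.03 and, matched on control, 0.09. By CPM, 2 genes of this list were at least 1.5-fold higher, 2 lower and 10 between. Most of its members had consecutive identifiers, from fabH (gene837) to fabI (gene847). Random lists draw scattered genes as if independent, so these percentiles can overstate how unusual such a run is. fabF (gene841) was 3.18-fold lower and fabZ (gene843) 10.1-fold lower, accC1 (gene844) was at -1.24, and fabI (gene847) was higher at 0.99. Secretion genes had 7 of 11 lower and 2 higher, a median of -1.39 and percentile 1.28 (4.675 when matched on control), and secA (gene555) was 2.62-fold lower.

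Nucleotide synthesis was the one list above the middle 95% of random lists matched on mean expression. Of 50 tested features 25 were at least 1.5-fold higher and 15 lower relative to the median gene, with a median of 0.79 and percentile 98.7. Matched on control expression it lay at 91.1, and it fell inside the range under 8 other settings, which ends that call. purA (gene252), for adenylosuccinate synthetase, was 8.07-fold higher (interval in log2 2.58 to 3.48), and nrdD (gene195), for the anaerobic ribonucleotide reductase, 15.2-fold lower. The carB features gene977 and gene1049 had 0 and 2 control counts and lie in the mirrored block. Their direction is uncertain, since counts of features with the same names in mirrored order may depend on how reads were assigned.

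The other lists lay inside the range matched on mean expression. DNA repair had 6 of 28 genes higher and 12 lower (median -0.27, percentile 64.4, and 99.0 when matched on control), with uvrA (gene563) 7.04-fold lower and the recG feature gene272 6.69-fold higher. DNA replication had 2 of 21 higher and 7 lower (median -0.40, percentile 43.3, and 96.3 when matched on control). Proteolysis and peptide uptake had 7 of 26 higher and 12 lower (median -0.39, percentile 73.0, and 98.1 when matched on control), with pepC (gene1601) 2.31-fold lower. Cell wall synthesis had 2 of 26 higher and 16 lower (median -0.83, percentile 21.0, and 76.5 when matched on control), and cell division had 0 of 8 higher and 5 lower (median -0.67, percentile 14.97, and 46.6 when matched on control). Redox genes had 3 of 6 higher and 3 lower (median -0.58, percentile 32.4, and 54.9 when matched on control), and the thioredoxin gene trxA (gene1478) was 11.9-fold lower and the methionine sulfoxide reductase gene msrB (gene1800) lower at -3.58. The 4 tested multidrug export features were all higher (median 2.17), and of 4 exopolysaccharide features 2 were higher and 1 lower (median 0.67). Lists this small got no percentile. The export features had 27, 5, 3 and 37 control counts, and genes this scarce in the control were commonly higher. Across tested genes, Spearman's rho between control CPM and the log2 ratio was -0.827, but control CPM is part of both values. The 220 genes with the fewest control counts (0 to 7) had a median log2 CPM ratio of 4.30. The minimum of 50 counts over both libraries fixes that direction, since a gene this scarce passed only through its rifampicin counts. No feature name matched the transposase list.

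**Figure D2:**
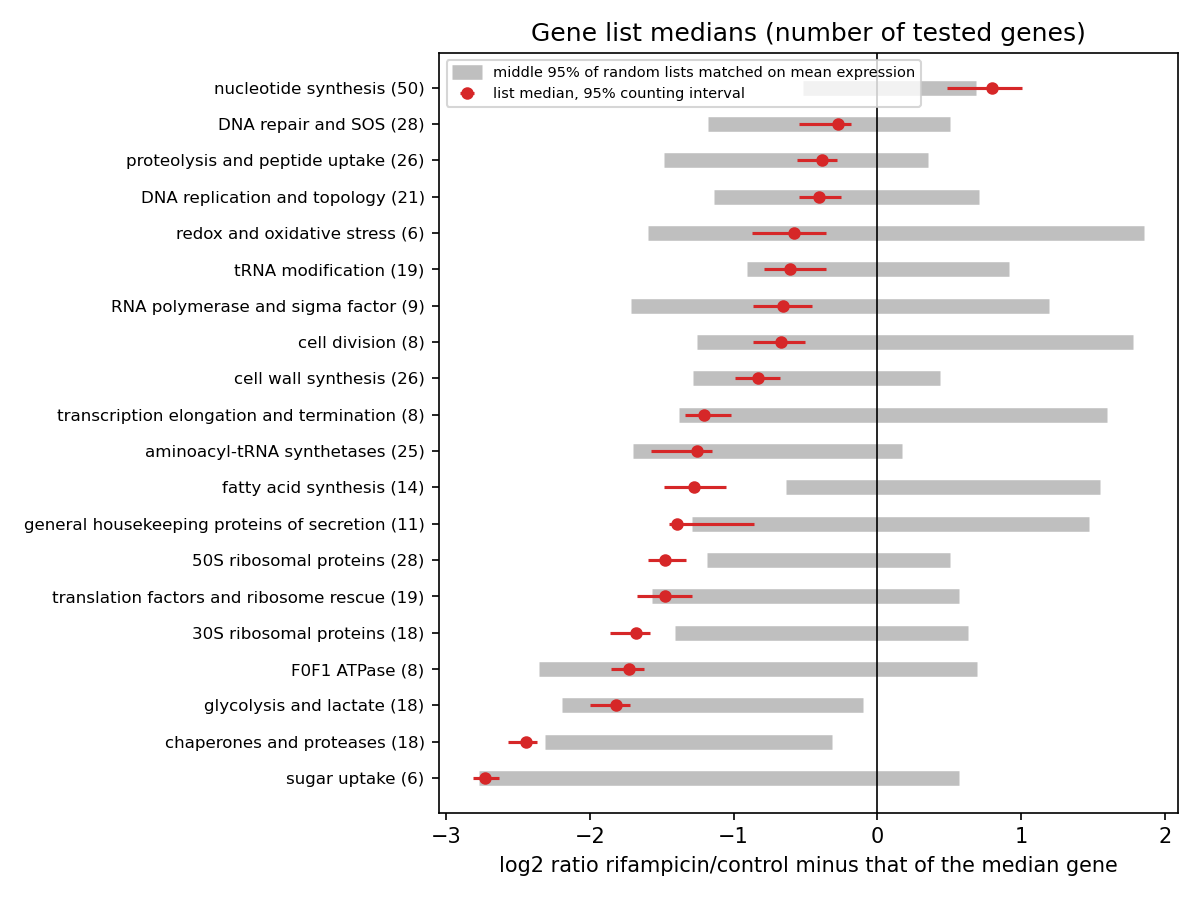
Median log2 ratio of rifampicin to control minus that of the median gene (x axis) for the 20 gene lists with at least 5 tested genes, with 95% counting intervals; grey bars hold the middle 95% of 10000 random lists matched on mean expression. Chaperone, ribosomal protein, fatty acid and secretion lists lie left of their bars, and nucleotide synthesis lies right of its bar.

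Of the 20 lists with a percentile, 5 lay below and 1 above the middle 95% of random lists when matched on mean expression, where 1 outside would be expected by chance. Matched on control expression, 1 lay below and 2 above. Fatty acid synthesis alone lay outside, and on the same side, under both ways of matching, so the chaperone, ribosomal protein and secretion lists were not set apart from genes of like abundance in the control. The fatty acid percentiles carry the limit given above for members with consecutive identifiers.

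The lowest features with a symbol, besides those above, included engB (gene725), a GTPase gene, 15.6-fold lower, gnd (gene2019), for 6-phosphogluconate dehydrogenase, 14.9-fold lower, and the copper transporter homologs copB (gene1137) and pacS (gene604), 10.5-fold and 12.1-fold lower. The lowest of all features had no symbol: gene632 had 4194 control counts and 18 after rifampicin, and gene1960 had 1765 and 113. The highest feature, gene749, had 0 control counts, which allows up to 3, and 30137 after rifampicin (4.86% of gene counts), at least 3063-fold higher relative to the median gene at 3 control counts (exact interval in log2 from 11.28). Of the 12 highest features with a symbol, dppA gene1565, a peptide-binding protein homolog, was 20.5-fold higher with 18 control counts. metAA gene1084 was 43.0-fold higher from 4 and 564 counts (interval in log2 4.06 to 7.31), with 33.7% of its rifampicin counts in 3 barcodes. Of these 12 features, fccA gene1026, osm1 gene1027, abgR gene1028, yxdM gene1030, yoeA gene982 and carB gene977 lie in the mirrored block; the others were PA3311 gene869, SPAC17G8.02 gene761, CBU-0006 gene406 and YJL218W gene1112. Among all tested genes 42 had 0 control counts and 0 had 0 rifampicin counts.

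At an equal depth of 24 gene counts per cell, the median control cell held 20 genes and the median rifampicin cell 22; unthinned, the medians were 80 and 34. A groL count was seen in 90.2% of 3326 thinned control cells (89.1 to 91.2) and 34.3% of 3459 thinned rifampicin cells (32.7 to 35.9), against 97.2% and 51.8% unthinned. For dnaK the thinned shares were 34.2% and 11.6% (unthinned 2722 of 3535 cells and 24.8%), for tuf 52.6% and 25.4% (unthinned 89.9% and 41.8%), and for rpoB 10.1% and 7.52% (unthinned 40.5% and 20.1%). For rpoC they were 7.55% (6.67 to 8.50) and 7.92% (7.04 to 8.87), a difference not detectable at this depth. No cell in a culture of 1 strain lacks these genes, so free RNA in droplets could not be measured.

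Counts of a gene were spread less evenly over barcodes in the rifampicin library than in the control. Repeated counts of 1 molecule and differences between cells both raise this measure and cannot be told apart here. In the control, the variance of 242 genes at equal depth was close to that of cells redrawn from the pooled profile, with a median relative variance of 1.03, a highest value of 1.29 (gap) and 0 genes over 1.5. The next in the control were clpC (gene1929) at 1.23, gene632 at 1.19 and groL at 1.17, against a highest value of 1.15 for any gene in redrawn control cells. After rifampicin the median over 420 genes was 1.18, and 122 genes (29.0%) exceeded 1.5. The highest were metAA gene1084 at 5.12, the tRNA modification gene mnmG (gene2021) at 5.03, gene137 at 4.49, BQ2027-MB1304C (gene1871) at 4.45 and vanR (gene1869) at 4.28. In the rifampicin library the median gene with 50 to 499 counts had 7.95% of its counts in 1 barcode, against 3.70% in cells redrawn at the same depths; in the control the values were 2.10% and 1.45%.

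**Figure D3:**
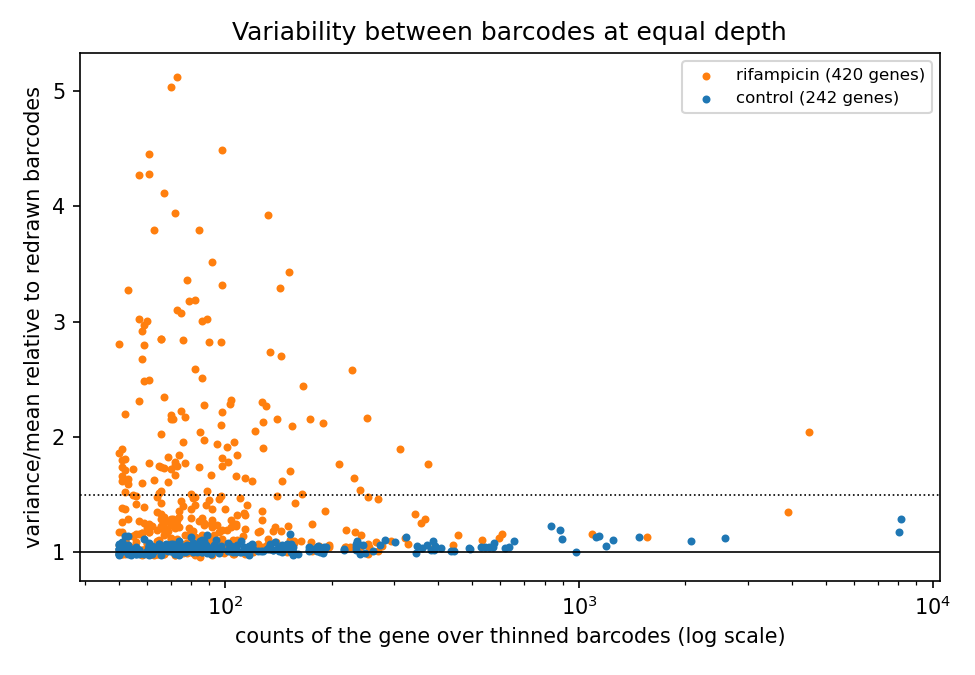
Variance over mean of each gene at 24 counts per cell, divided by that of redrawn cells (y axis), against the gene's thinned counts (x axis, log scale), for 242 control genes and 420 rifampicin genes, 1 point per gene. No control gene exceeds 1.29, and 122 rifampicin genes lie above the dotted line at 1.5.

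Clustering gave 11 groups of control cells (modularity 0.508), against 13 (0.606) for redrawn cells, and the highest held-out fold of a leading gene was 3.05 (rpsC in cluster 10), against 1.96. In 4 of 5 other settings 0 control clusters reached a held-out fold of 3, so no control cluster is described further. In the rifampicin library 2422 cells fell into 17 clusters, and each had a gene at least 3-fold higher in the held-out counts. The highest were gene1156 in cluster 7 (67.5-fold, 30 held-out counts), gene1295 in cluster 10 (58.0-fold), gene132 in cluster 12 (45.0-fold) and xseB, an exonuclease subunit gene, in cluster 6 (41.3-fold). Repeated counts of 1 molecule would fall in both portions and raise such folds. With each gene counted at most 1 time per cell, a setting added after the result was seen, 0 of 15 rifampicin clusters reached 3 (highest 2.82), against 1 of 15 for redrawn cells (highest 3.01). That setting lowers held-out folds by itself: for 20 genes raised together in simulated cells it gave no cluster past 3 at 6-fold (highest 2.77) and 2 at 20-fold (highest 6.44). Whether the rifampicin clusters reflect cell states or repeated counts therefore stays open. The control and rifampicin clusters were made separately and were not matched.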

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

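Of the tests in this part, the one that counted each gene 1 time per cell was written down before its result was seen; the others were chosen after.

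Some counts lay in data that the comparisons did not use. Features gene45 to gene48 took 84.0% of all control counts and 0 of the rifampicin counts, which allows up to 0.000232% (3 counts) for rifampicin. In the rifampicin file, rRNA features took 39.4% of all counts, tRNA features 8.85% and features with an nc identifier 3.79%; the control file lists no such features, so these have no control level.

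The first pattern is the flatter profile after rifampicin, in which the 100 most abundant genes took 34.6% of gene counts against 64.8% in the control. Low-count barcodes do not account for it, since the 370 rifampicin barcodes that reached the lowest control total of 621 counts gave 34.2%. Counting each gene at most 1 time per cell at equal depth closed -0.707% of the gap, so repeats within a barcode found no support. That setting converted the share of cells with a gene to a mean count under Poisson counting. Cells were thinned first, so repeated counts could still have displaced other genes. Copies of 1 molecule in several barcodes would also remain, so repeated counts are not excluded in general. An equal background for every gene is excluded as the whole cause: among 391 genes with 7 or fewer control counts, the 90th percentile of rifampicin barcodes with a count was 33.7 times the 10th, against at most 1.5 in 1000 simulated even backgrounds. A background that follows gene length, such as DNA, could not be tested because the files give no lengths. An effect of the drug, of the additional 3 h or of different library preparation and counting stays open and may act together, since the design confounds them.

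The second pattern is the set of genes counted after rifampicin and at 0 in the control. In the mirrored block, whose limits come from names alone, 35 of 43 features with at least 20 rifampicin counts (81.4%) were at 0 in the control, against 40 of 1841 other features (2.17%). The 9 features between the arms of the block had 1122 control counts and 0% of them were at 0, which argues against a silent stretch of the chromosome in the control. A candidate explanation is that reads matching both copies were dropped in the control file and kept in the rifampicin file. It does not reach the other 40 features, gene749 among them.

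The third pattern is that rifampicin barcodes shared their first 16 bases. Of 987 first parts, 161 occurred with all 12 last parts of 4 bases, against at most 0 in 100 random pairings. These barcodes were 42.5% of all and held 73.6% of the counts. The pairings drew evenly among the first parts seen, so they exclude even pairing only. First parts that occur at unequal rates were not simulated, so combination at random stays possible. In the control, 3350 of 3437 first parts occurred 1 time. Such even pairings gave a median of 1419, but they can leave first parts unused, while all 3437 were seen by definition. That contrast therefore says nothing about how control barcodes were combined. Spread of molecules among barcodes with the same first part found little support in a test on rare genes. These recurred in the deepest barcode of the same group 0.760 percentage points more often than in groups next in depth (bootstrap interval -0.0438 to 1.58). Depth went together within groups, however. Across the 161 first parts, Spearman's rho between the counts of the deepest barcode and the sum of the others was 0.822. The deepest barcode held a median of 41.7% of its group's counts. These values do not tell spread of molecules from cells that shared a droplet. Pairs of barcodes with the same rare gene and different first parts shared the last part 1.199 times as often as redrawn cells, which lies between the bounds set for that test, so spread within a last part and cell differences cannot be told apart. Whether 1 barcode was 1 cell in this library, or many cells shared a droplet, stays open.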

How the results depend on the processing

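All settings here were planned, except the control-file denominator, the removal of the mirrored block and of features at 0, the 2 restrictions by control minimum and by barcode part, the count of 1 per gene and cell, and matching on control expression, which were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and leaving out a replicate was not possible for the same reason.

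Scaling decided the counts of 2-fold genes. With CPM over all features 1534 genes were higher and 5 lower, with the median gene set to 1 the counts were 560 and 504, and with the 4 control-file features in the denominator 1705 and 2; those denominators shifted the median log2 ratio by 1.59, -1.31 and 2.65. A minimum of 200 counts gave 526 higher genes, thinning gave 301 and counting each gene 1 time per cell gave 261, with 1091, 720 and 671 genes tested in place of 1756. A 1.5-fold threshold gave 224 lower genes. In the remaining settings both counts stayed within 1.5 times the main ones.

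The chaperone, 30S and 50S medians stayed below the median gene in every setting run. In that order they were -2.20, -1.33 and -1.03 with 200 counts, -2.27, -1.51 and -1.22 without the deepest 5% of barcodes, -1.97, -1.18 and -0.74 with thinned cells, -2.23, -1.41 and -1.32 with rifampicin barcodes at the control minimum, and -1.80, -0.94 and -0.65 with 1 count per gene and cell. The chaperone and 50S medians were -2.60 and -1.63 with no minimum and -2.28 and -1.22 without barcodes whose first part had every last part, the 30S and 50S medians -1.51 and -1.20 with equal weight per cell, and the chaperone median -2.36 without the mirrored block. The cause of these moves was not tested. The fatty acid list stayed below the middle 95% of random lists in every setting with enough tested members, with a percentile of at most 0.535; thinned cells left too few. The 50S list moved inside the range of random lists with thinned cells (percentile 22.4) and with 1 count per gene and cell (20.1). The nucleotide synthesis median was 0.47 without the mirrored block, and the number of lists above the middle 95% of random lists was 0 there, with 200 counts, without the deepest barcodes, with equal weights, with thinned cells, with either barcode restriction and with 1 count per gene and cell. Lists below the middle 95% numbered 2 with thinned cells and with 1 count per gene and cell. Matching on control expression left 2 lists above and 1 below. The secretion list reversed to 0.018 with 1 count per gene and cell, where 4 members were tested.

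Among values for single named genes relative to the median gene, 1055 stayed within their counting interval, 429 moved outside it, and 3 for genes past 2-fold changed side. The 1055 include all values under settings that changed only the denominator. Values relative to the median gene cannot move there, so the 1055 overstate how stable the values were. tadA (gene1513), with 65.0% of its rifampicin counts in 3 barcodes, was at -0.22 without the deepest barcodes and -0.32 with equal weights, against a main value above 1, and atpA (gene654) at 0.039 with 1 count per gene and cell. Genes nearer to the median gene also changed side and are counted among those that moved or stayed, such as rpoA (gene381), at 0.25 with 1 count per gene and cell against -0.66. The difference in the share of cells with rpoC was -10.3 percentage points without thinning, opposite to the thinned value, as depth per cell differed.

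The difference in mean genes per cell, rifampicin minus control, was 1.45 at 24 counts, 2.56 at 42 counts and -7.81 without thinning. Median relative variance after rifampicin was 1.46 at 42 counts, where 258 of 535 genes (48.2%) exceeded 1.5 and the highest was 17.5. The rRNA share of the rifampicin counts was 38.3% with barcodes of at least 100 counts and 44.0% without the deepest. Control clusters with a held-out fold over 3 numbered 0 at resolution 1.5, 0 with all genes 0 with a second split and 0 with 1 count per gene and cell, and rifampicin clusters numbered 11 with all genes. Cells redrawn from the rifampicin profile gave 0 such clusters in the main setting, but 1 at resolution 0.5, 1 with the second split and 2 with all genes, where observed cells gave 13, 18 and 11. With 1 count per gene and cell, set before the split, observed rifampicin cells gave 0 and redrawn cells 1. In simulated cells with 20 genes raised together 6-fold that setting gave 1 cluster mostly of that state, with 36.4% of its cells (45.2% with all counts) and a highest held-out fold of 2.77, under the threshold, and it hides a gene that was high by itself, so the 0 does not tell cell states from repeated counts. Depth limits what can be seen per cell: 1092 of 4551 rifampicin barcodes had under 24 gene counts.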

Other observations

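Purine synthesis features, singled out after their values were seen, were mostly higher. Of 13 tested features named for steps of the pathway (the repressor gene purR left out), 12 were at least 2-fold higher relative to the median gene and 0 were 2-fold lower, with a median of 1.39. They had 354 control and 3642 rifampicin counts together. Their median lay at percentile 97.0 of random lists matched on mean expression and 74.0 of lists matched on control expression, so genes as scarce in the control were about as much higher.

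Barcodes were also grouped by their last 4 bases into what are called pools here, of which 8 occurred in both libraries. The split of the barcode was set here. What these bases mark, or whether the same ending links the 2 libraries, was not known. The median log2 CPM ratio ranged from -0.84 in the pool ending in CGAA to 2.38 in the pool ending in CTCT. Each pool's median covered its own genes with at least 50 counts, from 106 to 989 genes, so the medians are not alike. The pools ending in CGAA and CAGG had more genes 2-fold lower than higher (85 against 44, and 172 against 141). In the other pools more genes were higher. The log2 CPM ratio, not set against the median gene, of groL was below 0 in 8 of 8 pools, from -3.71 to -2.36, that of dnaK in 8 of 8, from -4.41 to -1.16, and that of purA above 0 in 8 of 8, from 1.95 to 6.12. Of 60 named genes with enough counts in all 8 pools, 48 had the main direction in every pool, and 4 had it in 5 or fewer: pepC, secA and thiI, with main CPM ratios near 0, and ftsZ, which had it in 2 of 8. These pools are parts of 1 library per group and no replicates.

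In the control, 588 barcodes (16.6%) had under 8% of their counts in the gene features used, against 1 rifampicin barcode. The asparagine synthetase homolog Asns (gene863) was taken into the aminoacyl-tRNA synthetase list because its name matches asnS without case. It was higher relative to the median gene at 2.81, and it was the 1 member of that list counted as higher.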
